A study of Drosophila melanogaster with 23 samples.

How the data were processed

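The series holds 23 bulk RNA-seq libraries of hearts removed from Drosophila melanogaster. Per the labels' protocols, RNA was extracted with a miRNeasy kit after flash freezing in Quizol, and libraries were made with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA and keeps the strand. The labels put the libraries in 5 groups: w1118 at 1 week (n = 4), w1118 at 5 weeks (n = 4), attp2 at 1 week (n = 5), attp2 at 5 weeks (n = 5) and Lamin C RNAi at 1 week (n = 5). Both strains are controls. The RNAi was expressed from the promoter of Hand, a transcription factor gene of the heart. The labels do not say that libraries of a group came from separate pools of animals, so p-values measure the spread between these libraries, part of which may be technical.

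Per the submitters' processing notes, cutadapt, STAR, DESeq2 and the dm6 genome build were used. Their versions, the read counter, its strand setting and the gene annotation are not given in the sources used here. The authors deposited a table of raw counts per gene symbol for each of 2 sets of libraries, the 8 w1118 libraries and the 15 attp2 and Lamin C RNAi libraries. The authors' other values are on a log2 scale. Checked against the counts, these log2 values were log2 of the count divided by a factor per library, plus 1, and the factor equalled the size factor that DESeq2 computes from the same counts. Tests were run on the deposited counts. Reads of near-identical genes (the Hsp70, Cyp6a, GstD, actin, trypsin and ribosomal protein families) and of overlapping or antisense genes may have been split in ways that cannot be checked from the tables.

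Gene coordinates were taken from the BDGP6.54 annotation, 1-based, by symbol. Of the 17104 symbols, 13264 matched a current symbol, 3700 an older one and 140 none. A position was found for 217 of the 218 genes that the rules below name. The annotation release used by the authors is not given in the sources used here.

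Total counts per library were 33.4 to 52.5 M (M, mega) for w1118 at 1 week, 21.8 to 48.5 M for w1118 at 5 weeks, 45.1 to 77.1 M for attp2 at 1 week, 48.3 to 90.0 M for attp2 at 5 weeks and 48.1 to 74.2 M for Lamin C RNAi. At these depths a gene at 10 CPM is far above counting noise in each library, so the spread between libraries, not counting error, limits the precision of the genes named. Every pair of libraries of a group was compared by a chi-square per gene, which was at least 62.9 where sampling noise alone gives 1, so no library was counted as a copy of another.

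Differences between groups were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, on genes kept by filterByExpr and with TMM scaling. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and 0.05 was the threshold. All adjusted p-values of single genes are from this test unless another tool is named. The w1118 table was fitted alone (9631 genes). The 3 groups of the attp2 table were fitted together (10044 genes) and gave age in attp2, Lamin C RNAi against attp2 at 1 week, and Lamin C RNAi against attp2 at 5 weeks. The difference of the age effect between the strains was tested as an interaction over the 18 control libraries (10387 genes); strain and table cannot be told apart, so no other strain effect was tested. Standard errors of log2 fold changes were the size of the fold change divided by the square root of its F statistic. Levels are given as CPM on the TMM scale of each table, as mean ± SD over libraries.

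Gene lists were fixed before the data were examined, as were the groups, tests, named-gene rule and the first set of alternatives. The 16 biology lists covered the nuclear lamina and envelope, cardiac transcription factors, sarcomere, ion channels and calcium handling, extracellular matrix and adhesion, oxidative phosphorylation, tricarboxylic acid (TCA) cycle, glycolysis, lipid metabolism, antimicrobial peptides and immune signalling, chaperones, antioxidant and detoxification genes, cytosolic ribosomal proteins, proteasome, autophagy and the circadian clock. The 9 marker lists covered nephrocytes, fat body and oenocytes, haemocytes, body wall and flight muscle, neurons, the male reproductive tract, ovary and eggs, gut and Malpighian tubule. Quality lists held mitochondrially encoded genes and replication-dependent histones. Members were matched by symbol: 10 of 17 TCA cycle genes, 32 of 36 lipid genes, 41 of 44 immune genes, 24 of 25 lamina genes and 27 of 28 matrix genes were found, and all members of the other biology lists given by name. No mitochondrially encoded gene was found, and the 111 histone symbols had too few counts to test; 1 gene of the male tract list was tested in the attp2 table and 0 in the w1118 table. Lists were tested with camera of limma 3.58.1 on log CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted within the biology or the marker lists of a comparison. Camera with an estimated correlation and fry were the alternatives. In splits that mixed the groups, camera with the preset correlation still passed a median of 5.5 (w1118 age), 6 (attp2 age) and 6 (Lamin C RNAi) of the 16 biology lists. A pass of camera alone therefore does not show that a list shifted. With DESeq2 size factors, 0 of the 74 list medians in the 3 main comparisons changed sign.

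The genes named follow a rule. LamC and Lam come first. Then, for each comparison, come the 8 genes per direction with the largest fold change among those past the threshold, whose libraries do not overlap between groups, with a mean of at least 10 CPM in the higher group and a symbol that is more than a CG or CR number. Then come up to 4 members of each biology list and up to 2 of each marker list by p. Overlaps name 6 genes per direction and the interaction 4. The rule read CPM of total counts, while the CPM printed use the TMM scale.

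The alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter on low counts, a filter at 5 CPM, a cut of the called genes at a log2 fold change of at least 1 in size, fits of only the groups compared, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were the removal of 4 libraries with over 1000 summed CPM of gut markers, and covariates for gut markers and for heat shock genes. Tested on simulated data with 50 genes per fold size among 9487 to 10243 genes, the w1118 fit recovered 60% of 2-fold and 82% of 4-fold changes, the attp2 age fit 52% and 80%, the Lamin C RNAi fit 56% and 88%, the comparison of Lamin C RNAi with 5 weeks 62% and 74%, and the interaction 34% and 78%. False calls were 2.48%, 2.68%, 6.92%, 1.75% and 1.14% of calls, in that order, against 14.5%, 17.6%, 23.2%, 13.5% and 13.6% with DESeq2.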

Results

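Hearts of 2 control strains of Drosophila melanogaster, w1118 and attp2, were sequenced at 1 week and 5 weeks of age, together with hearts at 1 week labelled LamC RNAi. Median depth was 48.9 and 47.3 M counts (M, mega) in w1118 at 1 and 5 weeks, 51.6 and 60.6 M in attp2, and 58.5 M in the libraries labelled LamC RNAi. Between 10794 and 11928 genes had counts in a library. The libraries held abundant transcripts of tissue that lies against the heart. Cyp4g1, an oenocyte cytochrome P450, took 14.5% ± 2.81 of counts in attp2 at 1 week (SD, n = 5), 13.1% ± 1.14 at 5 weeks and 10.8% ± 2.71 in the libraries labelled LamC RNAi. It took 8.33% ± 1.80 and 8.20% ± 1.21 in w1118 at 1 and 5 weeks (n = 4 each).

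LamC encodes Lamin C, the A-type lamin, on chromosome 2R from 14570810 to 14575771, and was the target of the RNAi. Its level was 186, 222, 138, 148 and 163 CPM in the attp2 libraries at 1 week and 155, 199, 87.4, 172 and 132 CPM in those labelled LamC RNAi. The means were 171.2 ± 33.6 and 149.1 ± 42.4 CPM (SD, n = 5 each). The log2 fold change of −0.20 ± 0.20 (SE) was within the spread between libraries (adjusted p = 0.628, exact permutation p = 0.405), with 95% bounds of −0.64 and 0.24. The transcript therefore did not check the RNAi label, and LamC RNAi is used below only as the name that the libraries carry. The log2 fold change became −0.09 without attp2 1-week library 2, −0.33 and −0.06 without libraries 2 and 3 labelled LamC RNAi, −0.13 without the 4 libraries with gut transcripts named below and −0.33 with a covariate for heat shock genes. LamC was 249, 251, 246 and 277 CPM in w1118 at 1 week and 200, 198, 190.0 and 207 CPM at 5 weeks, with means of 255.8 ± 14.5 and 198.6 ± 6.87 (SD, n = 4 each). All 4 older libraries lay below all younger ones (log2 fold change −0.37 ± 0.10, exact permutation p = 0.0286, the smallest that 4 against 4 libraries allow). The adjusted p of 0.05001 lay just above the threshold; it was 2.6e-04 with DESeq2, 0.0444 with DESeq2 size factors and 0.0466 with the 5 CPM filter. It reached 0.135 under the others, apart from the cut at a log2 fold change of at least 1 in size, which is no test of its own and which LamC lay below. In attp2 at 5 weeks LamC was 148, 185, 118, 122 and 127 CPM, with a mean of 140.1 ± 27.9 (log2 fold change −0.29 ± 0.20, adjusted p = 0.362, and −0.18 without 1-week library 2). Lam, the B-type lamin on chromosome 2L from 5542480 to 5546642, had means of 23.1 and 25.3 CPM in w1118 and 25.3 and 25.3 CPM in attp2 at 1 and 5 weeks. It averaged 32.1 ± 9.22 CPM in the libraries labelled LamC RNAi (log2 fold change 0.34 ± 0.14, adjusted p = 0.214), where 1 library, number 3, had 47.3 CPM. Without it the log2 fold change was 0.16, and 0.17 without the 4 libraries with gut transcripts. Its log2 fold changes with age were 0.14 (adjusted p = 0.645, from 0.03 without 5-week library 4 to 0.21 without 5-week library 1) in w1118 and −0.00 (adjusted p = 0.998) in attp2.

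**Figure D1:**
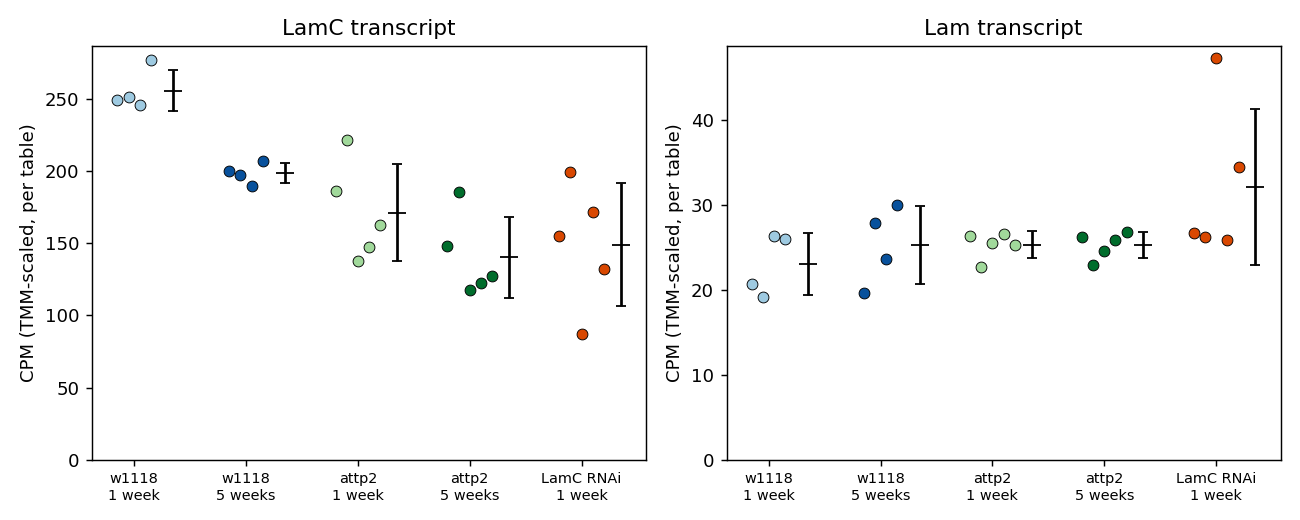
LamC (left) and Lam (right) transcript levels in CPM on the TMM scale of each table, with 1 point per library in 5 groups and mean ± SD beside the points. The LamC points of the libraries labelled LamC RNAi, 87.4 to 199 CPM, overlap those of attp2 at 1 week, 138 to 222 CPM.

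The series asked which genes change with age in w1118 hearts. PGRP-SC1b, a peptidoglycan-degrading amidase on chromosome 2R from 8713446 to 8715094, rose from 0.779 to 67.6 CPM (log2 fold change 6.37 ± 0.69 SE, adjusted p = 0.00102). The 1-week mean was raised by library 3, with 2.27 CPM against at most 0.352 elsewhere. The drosomycin-like peptide gene Drsl5 rose by 5.08 ± 0.29 on the log2 scale, and the immune-induced gene edin by 3.94 ± 0.45. The glutathione transferase gene GstD5 rose by 3.47 ± 0.50, Pal2, an enzyme of peptide amidation, by 3.16 ± 0.32 and the antifungal peptide gene Drs by 3.07 ± 0.69. RpS5b, a ribosomal protein gene of the germline, rose from 0.671 to 11.3 CPM and the odorant-binding protein gene Obp56d from 1.51 to 15.5 CPM. In both, 1 library stood far above the others at 5 weeks. RpS5b was 33.8 CPM in library 2 and at most 5.14 elsewhere, and Obp56d 35.1 CPM in library 3 and at most 9.73 elsewhere. The prophenoloxidase genes PPO2 and PPO1, which serve melanization in crystal cells, fell from 438 to 30.1 CPM and from 349 to 29.7 CPM (log2 fold changes −3.87 ± 0.55 and −3.56 ± 0.63, adjusted p = 0.00347 and 0.00886). NimC4, a phagocytic receptor, fell by 4.03, the cuticle protein gene Cpr49Ae by 3.39 and Whamy, a regulator of actin assembly, by 2.79 on the log2 scale. The Notch target E(spl)mbeta-HLH fell by 2.69, the peroxidasin gene Pxn by 2.53 and lectin-33A by 2.38 on the log2 scale. Of the 9631 genes tested, 502 were higher and 356 lower at 5 weeks, and the libraries of the 2 ages did not overlap for 1575 genes (16.4%, chance gives 2.86%). These counts fell by over 1.5 times without any of 5 single libraries. They were 273 and 159 without 1-week library 1, 174 and 124 without 1-week library 2 and 260 and 172 without 1-week library 3. They were 235 and 194 without 5-week library 1, and 250 and 204 without 5-week library 2. RpS5b lost its call without 1-week library 1, 2 or 3 (adjusted p 0.0639 to 0.0833). Drs lost it without those or 5-week library 1 or 2 (0.0571 to 0.0854), and Obp56d without those 5 or 5-week library 3 (0.0504 to 0.0897).

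By list, the sarcomere fell in w1118. Of its 26 tested members 7 were lower and 0 higher, and 12 were lower when adjusted over the list alone (camera adjusted p = 4.5e-09, adjusted p = 0.558 with an estimated correlation). The myosin heavy chain gene Mhc fell by 1.10 ± 0.19 and TpnC47D, a troponin C gene, by 1.43 ± 0.14 on the log2 scale. Unc-89, the fly obscurin gene, fell by 1.22 ± 0.22 and Mlc1, a myosin light chain gene, by 0.62 ± 0.14 on the log2 scale. Cardiac transcription factors had bap (−1.11), H15 (−0.76) and tin (−0.86) lower of 19. When adjusted over the list alone, 4 were lower (camera adjusted p = 0.00731, adjusted p = 0.558 with an estimated correlation). Among 31 ion channel and calcium genes, 4 were lower and 2 higher (13 and 3 when adjusted over the list alone, camera adjusted p = 0.00389, adjusted p = 0.558 with an estimated correlation). The ryanodine receptor gene RyR fell by 1.07 and the potassium channel gene slo by 0.94 on the log2 scale, while sei, the fly hERG gene, rose by 0.76 and nrv3, a sodium pump subunit gene, by 0.70. The oxidative phosphorylation list had a median of −0.27, with UQCR-C2 and UQCR-C1 of complex III lower among 57 members. When adjusted over the list alone, 0 were lower (camera adjusted p = 4.8e-10, adjusted p = 0.558 with an estimated correlation). The TCA cycle had 1 lower of 10, aconitase (Acon, −0.49), and 1 when adjusted over the list alone. Glycolysis had 2 lower of 19, Treh (−0.67) and GlyP (−0.48), and 2 when adjusted over the list alone. Both lists had a camera adjusted p = 0.0434, and an adjusted p = 0.583 with an estimated correlation. The matrix list had the protease inhibitor gene Timp (0.47) higher and papilin (Ppn, −0.69) lower of 27 members. When adjusted over the list alone it also had 1 of each (median −0.17, camera adjusted p = 0.0131, adjusted p = 0.558 with an estimated correlation). Ribosomal protein genes shifted down by a median of −0.16 (1 higher of 81, RpS5b, and 0 when adjusted over the list alone, camera adjusted p = 9.7e-06, adjusted p = 0.583 with an estimated correlation).

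Immune genes moved up in w1118, with 8 higher and 1 lower of 41 (11 and 1 when adjusted over the list alone, median 0.47, camera adjusted p = 0.0127, adjusted p = 0.583 with an estimated correlation). The peptidoglycan recognition genes PGRP-SB1, PGRP-SC2 and PGRP-SD rose by 2.33, 2.33 and 1.95, and the antimicrobial peptide gene Mtk by 1.75 on the log2 scale. Of 37 antioxidant and detoxification genes 9 were higher and 2 lower (12 and 4 when adjusted over the list alone, camera adjusted p = 0.0466, adjusted p = 0.573 with an estimated correlation). The peroxiredoxin genes Prx2540-1 and Jafrac1 rose by 1.48 and 0.98, and Keap1, a repressor of the antioxidant response, fell by 0.83. The other 6 biology lists did not pass camera. The lamina list had 1 lower of 24, klar (−0.61), which links nuclei to microtubules (camera adjusted p = 0.143, 3 lower when adjusted over the list alone). Lipid metabolism had Mtp, which loads lipoproteins, higher (0.80) and Lsd-2, a lipid droplet protein gene, lower (−0.73) of 32 (camera adjusted p = 0.422, 0 and 1 when adjusted over the list alone). Chaperones had l(2)efl lower (−0.72) of 22 (camera adjusted p = 0.422, 1 when adjusted over the list alone). Autophagy had Atg3 higher (0.49) of 23 (camera adjusted p = 0.149, 1 when adjusted over the list alone). The clock had cyc higher (0.45) of 8 (camera adjusted p = 0.414, 1 higher and 1 lower when adjusted over the list alone). Of 31 proteasome genes 0 passed edgeR's test, 0 had an unadjusted p under 0.05 and 0 passed DESeq2 (camera adjusted p = 0.114). Among the marker lists, haemocyte genes moved with age, with 6 of 15 lower and 1 higher (7 and 1 when adjusted over the list alone, median −0.46, camera adjusted p = 0.00324, adjusted p = 0.138 with an estimated correlation). Their summed level went from 3443 ± 260.4 to 1910 ± 378 CPM. The body wall and flight muscle list was lower too (2 of 5 tested, flr and tnc, 3 when adjusted over the list alone, camera adjusted p = 0.0102, adjusted p = 0.138 with an estimated correlation). Whether flr and tnc are particular to these muscles was not tested, so less muscle RNA cannot be read from them. Ovary genes had a median of 2.03 with 0 of 11 past edgeR's threshold (5 at an unadjusted p under 0.05, with DESeq2 and when adjusted over the list alone, camera adjusted p = 0.0122, adjusted p = 0.423 with an estimated correlation). Their sum went from 5.03 to 23.03 CPM, and RpS5b moved with them. Nephrocyte (Klf15 higher, 1 of 9, adjusted p = 0.618), fat body and oenocyte (fit and Cyp6g1 higher, 2 of 16, 0.118) and neuron lists (0 of 9, also at an unadjusted p under 0.05 and with DESeq2, 0.618) did not pass camera. Nor did the gut (Amy-d higher and Mal-B1 lower of 12, 0.361) and Malpighian tubule lists (Best2 higher, 1 of 3, 0.492).

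Age was compared in attp2 as well, in a table of its own. Dro (drosocin, chromosome 2R from 14745961 to 14746714) rose from 24.7 to 1307 CPM (log2 fold change 5.73 ± 0.78 SE, adjusted p = 2.5e-04). Def (defensin) rose by 5.31 ± 1.13, edin by 5.11 ± 0.84 and the diptericin gene DptA by 5.00 ± 1.04 on the log2 scale. SPH93, a serine protease homologue, rose by 4.91 ± 0.99, nolo, a matrix protein gene, by 4.62 ± 0.43, Drs by 3.97 ± 0.52 and PGRP-SC1b by 3.70 ± 0.87 on the log2 scale. PPO1 (chromosome 2R from 17887220 to 17889973) fell from 639 to 21.96 CPM and PPO2 from 585 to 21.7 CPM (log2 fold changes −4.86 ± 0.69 and −4.76 ± 0.64, adjusted p = 3.6e-04 and 2.5e-04). The 5-week means were raised by library 2, with 76.8 CPM of PPO1 and 72.5 of PPO2, against at most 10.5 and 12.5 elsewhere. Cpr49Ae fell by 3.68, Pxn by 2.78, NimC4 by 2.72 on the log2 scale. ninaD, a scavenger receptor for carotenoid uptake, fell by 2.66 and kek1, an inhibitor of EGF signalling, by 2.65 on the log2 scale. The log2 fold change of the cuticle protein gene Cpr49Ab was −2.52. Of 10044 genes, 964 were higher and 1054 lower at 5 weeks, and 1833 did not overlap between the ages (18.2%, chance gives 0.794%).

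**Figure D2:**
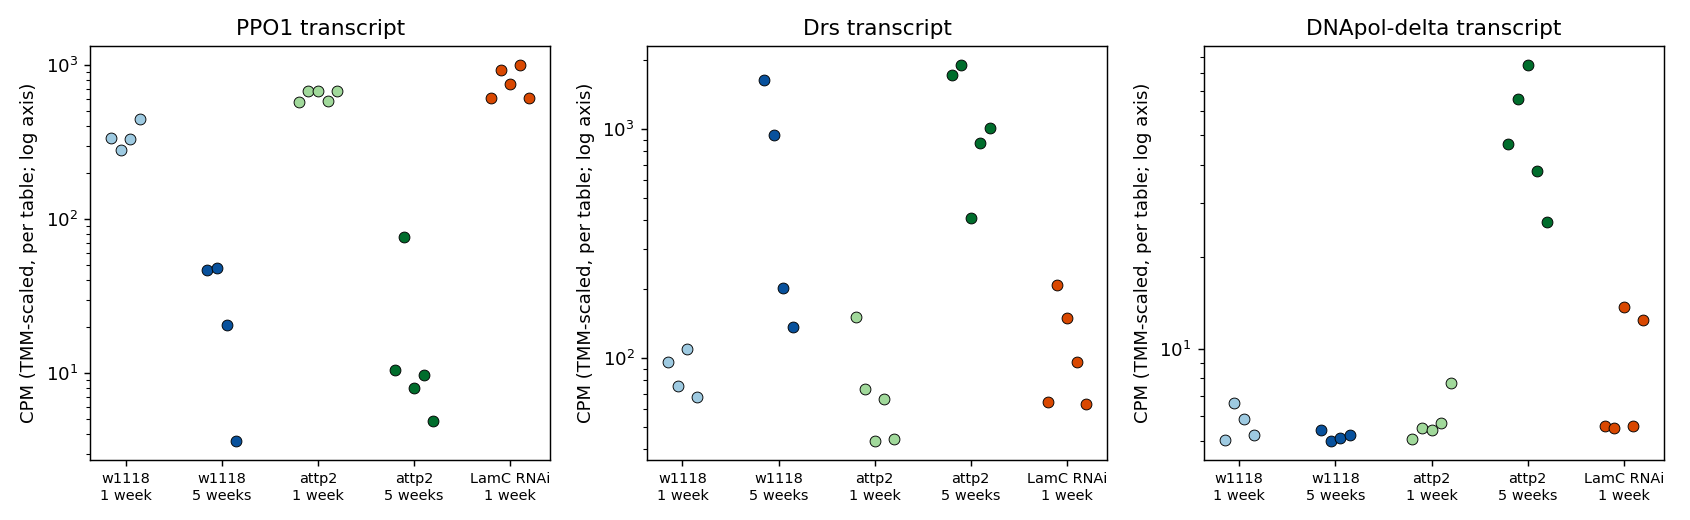
PPO1, Drs and DNApol-delta transcript levels per library in CPM on the TMM scale of each table (log axis), with 1 point per library in 5 groups. PPO1 is lower and Drs higher in every 5-week library than in every 1-week library of the same strain, while DNApol-delta is higher at 5 weeks in attp2 alone, where its interaction test passed.

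Energy metabolism lists moved down with age in attp2. Of 57 oxidative phosphorylation genes 51 were lower and 0 higher (52 when adjusted over the list alone, median −0.37, camera adjusted p = 5.7e-29, adjusted p = 0.118 with an estimated correlation). Their summed level went from 16362 ± 522 to 12238 ± 415 CPM (SD, n = 5 each). UQCR-C2 fell by 0.78 ± 0.06, ATPsynB, a subunit of ATP synthase, by 0.65 ± 0.06 and RFeSP of complex III by 0.52 ± 0.05 on the log2 scale. The TCA cycle had 7 lower of 10 (9 when adjusted over the list alone, camera adjusted p = 1.6e-06, adjusted p = 0.118 with an estimated correlation). Acon fell by 0.74 and the malate dehydrogenase gene Mdh2 by 0.64. Glycolysis had 13 lower of 19 (18 when adjusted over the list alone, camera adjusted p = 5.9e-10, adjusted p = 0.170 with an estimated correlation). The pyruvate kinase gene PyK fell by 0.70 and Gapdh1 by 0.59. Lipid metabolism had 18 lower and 1 higher of 32 (20 and 1 when adjusted over the list alone, camera adjusted p = 6.0e-08, adjusted p = 0.180 with an estimated correlation). The acetyl-CoA carboxylase gene ACC fell by 1.07 ± 0.19. Of 27 sarcomere genes 15 were lower (17 when adjusted over the list alone, median −0.41, camera adjusted p = 4.6e-11, adjusted p = 0.170 with an estimated correlation). TpnC47D fell by 1.64, Mhc by 1.05, Mlp84B, a muscle LIM protein gene, by 0.76 and Zasp52, a Z-disc gene, by 0.58. Cardiac transcription factors had 4 lower of 19, bap, H15, lbl and Doc3, and 4 when adjusted over the list alone (camera adjusted p = 0.00609, adjusted p = 0.265 with an estimated correlation). Among 31 ion channel genes 9 were lower and 3 higher (12 and 3 when adjusted over the list alone, camera adjusted p = 0.00536, adjusted p = 0.232 with an estimated correlation). RyR was at −0.79, the calcium pump gene SERCA at −0.50 and sei at 0.81. The matrix list had 10 lower and 1 higher of 27 (11 and 3 when adjusted over the list alone, camera adjusted p = 7.2e-04, adjusted p = 0.180 with an estimated correlation). SPARC, a collagen-binding protein gene, fell by 1.01 and the collagen gene Mp by 0.88.

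Of 80 ribosomal protein genes 21 were lower and 1 higher in attp2 (33 and 1 when adjusted over the list alone, median −0.19, camera adjusted p = 1.1e-09, adjusted p = 0.490 with an estimated correlation). RpL22 was at −0.61 and RpL38 at 0.36. Immune genes went up, with 17 higher and 1 lower of 41, also when adjusted over the list alone (median 0.62, camera adjusted p = 1.2e-04, adjusted p = 0.475 with an estimated correlation). PGRP-SC2 rose by 3.47 and Mtk by 2.79. The other 6 biology lists did not pass camera. The lamina list had Msp300 (−0.47), a giant protein that anchors nuclei in muscle, and klar (−0.40) lower and bocks (0.31) higher of 24, also when adjusted over the list alone (camera adjusted p = 0.541). Antioxidant genes had 6 higher and 1 lower of 38 (5 and 1 when adjusted over the list alone, camera adjusted p = 0.163), with GstE1 at 1.41 and the mitochondrial Sod2 at −0.48. Chaperones had Hop and Hsp60A higher and l(2)efl lower of 22, also when adjusted over the list alone (camera adjusted p = 0.645, median 0.01, mean −0.02). Autophagy had 3 higher and 1 lower of 23, also when adjusted over the list alone (camera adjusted p = 0.443), with the autophagy receptor gene ref(2)P at 0.70. The clock had cyc higher and cry lower of 8, also when adjusted over the list alone (camera adjusted p = 0.624), and 0 of 31 proteasome genes passed edgeR's test, an unadjusted p under 0.05 or DESeq2 (camera adjusted p = 0.163). Haemocyte genes fell beside these groups, with 11 of 15 lower and 1 higher (11 and 2 when adjusted over the list alone, median −0.89, camera adjusted p = 3.3e-06, adjusted p = 0.0185 with an estimated correlation). Their sum went from 3936 ± 374 to 1679 ± 123 CPM. The fat body and oenocyte list had 1 lower of 18, Desat1 (median −0.46, camera adjusted p = 0.0284, adjusted p = 0.594 with an estimated correlation). Body wall muscle (2 lower of 6, adjusted p = 0.0626), nephrocyte (1 higher and 2 lower of 9, 0.359), and neuron lists (1 lower of 9, 0.534, median 0.05, mean −0.11) did not pass camera. The same holds for the ovary (0 of 14, 0.777, median −0.04, mean 0.19), gut (0 of 20, 0.732) and Malpighian lists (0 of 5, 0.238). With edgeR, 0, 2 and 1 of their members had an unadjusted p under 0.05, and with DESeq2 0, 1 and 1 passed. Gut markers were unequal between libraries, summing to 400.3 to 19021 CPM at 5 weeks and 722 to 13623 CPM at 1 week. They passed 1000 CPM in attp2 1-week library 3 and 5-week libraries 3 and 4 and in library 3 labelled LamC RNAi. Without these 4 libraries 797 genes were higher and 752 lower with age in attp2.

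**Figure D3:**
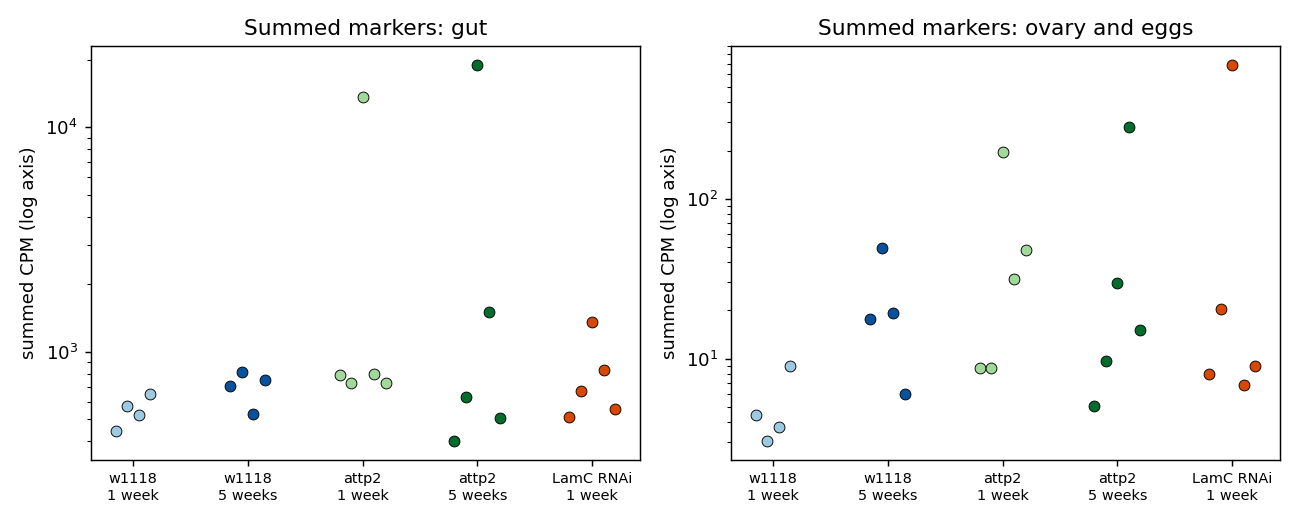
Summed CPM of the gut marker list (left) and of the ovary and egg marker list (right), with 1 point per library in 5 groups (log axes). Gut markers reach 13623 CPM in 1 attp2 library at 1 week and 19021 CPM in 1 at 5 weeks, and ovary markers 689 CPM in 1 library labelled LamC RNAi.

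The series next asked which age changes the 2 strains share. Of 9444 genes tested in both, 213 were higher in both strains and 189 lower in both, where independent lists of these sizes give 49.5 and 38.9 (exact hypergeometric p = 1.3e-88 and 3.7e-91), and 7 went opposite ways. The strains share no library. The hypergeometric p takes genes as independent draws and does not measure the spread between libraries, here and below. Ranked by the smaller of the 2 changes, the shared rises were led by edin, PGRP-SC1b, Drs and Pal2. They were followed by Syt7, a calcium sensor of vesicle fusion (2.72 ± 0.18 and 2.73 ± 0.25 in w1118 and attp2), and Dro (2.64 ± 0.56 and 5.73 ± 0.78). The shared falls were led by PPO2, PPO1, Cpr49Ae, NimC4, Pxn and lectin-33A (−2.38 ± 0.33 and −2.43 ± 0.38). Across genes, which are not independent replicates, the fold changes had a Pearson r of 0.555 and a Spearman rho of 0.451. The counts dropped by over 1.5 times without any of 5 w1118 libraries. They were 130 and 96 without 1-week library 1, 88 and 76 without 1-week library 2 and 122 and 107 without 1-week library 3. They were 112 and 119 without 5-week library 1, and 120 and 108 without 5-week library 2. The age effect itself differed between the strains for 79 of 10387 genes, 29 with a higher and 50 with a lower log2 fold change in attp2 (edgeR interaction test). DNApol-delta, the catalytic subunit of DNA polymerase delta (chromosome 3L from 15984322 to 15987815), had the smallest p of the difference. It went from 6.09 ± 1.16 to 54.2 ± 24.1 CPM in attp2 and from 5.497 ± 0.70 to 4.92 ± 0.17 CPM in w1118 (difference 3.31 ± 0.36 SE on the log2 scale, adjusted p = 3.3e-04). The AAA ATPase gene bor (0.92), Keap1 (0.96) and the valyl-tRNA synthetase gene ValRS (0.82) had higher fold changes in attp2. Lower ones were found for Kaz1-ORFB (−1.70), Men, a malic enzyme (−1.31), the kinase gene Drak (−0.87) and uzip (−0.64), with adjusted p from 0.00529 to 0.0289 for these 7. The count of 79 became 44 without attp2 1-week library 3 and 17 without library 4, and 45, 42 and 19 without attp2 5-week library 1, 3 and 5. It became 17, 11, 16 and 271 without w1118 1-week library 1, 2, 3 and 4, and 47, 119 and 32 without w1118 5-week library 1, 3 and 4.

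**Figure D4:**
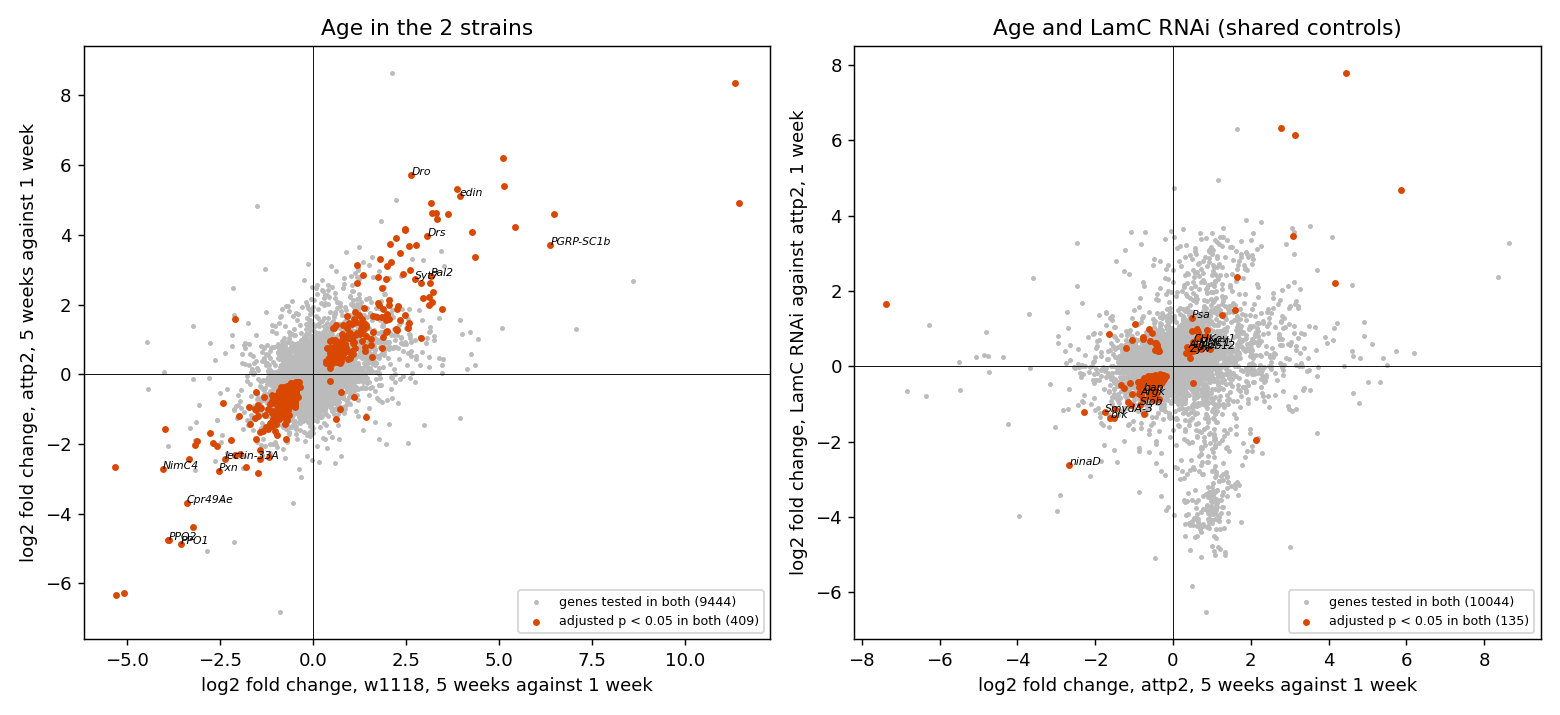
Log2 fold change per gene, with age in w1118 against age in attp2 (left, 9444 genes) and with age in attp2 against LamC RNAi (right, 10044 genes); orange points passed the threshold in both comparisons and the genes the overlap rule names are written beside theirs. Of the 409 orange points at left all but 7 went the same way in both strains, and 20 of 135 at right went opposite ways.

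LamC RNAi was compared with attp2 at 1 week, both at the same age. Fewer genes differed than with age, and the target LamC was not among them. The photolyase gene phr, which repairs UV damage (chromosome 2R from 7825289 to 7827319), rose from 1.14 to 13.7 CPM in the libraries labelled LamC RNAi (log2 fold change 3.58 ± 0.16 SE, adjusted p = 2.7e-08). The laminin subunit gene wb rose by 2.22 ± 0.36, Psa, an aminopeptidase gene, by 1.29 ± 0.14, jtb by 0.88 ± 0.12 and the cytochrome P450 gene Cyp6a17 by 0.88 ± 0.16 on the log2 scale. The phagocytic receptor genes NimC2, NimC1 and Sr-CI rose by 1.53, 1.13 and 0.99; they are expressed in haemocytes. ninaD (chromosome 2L from 18081628 to 18083608) fell from 20.9 to 3.39 CPM (−2.62 ± 0.32, adjusted p = 7.8e-04). sosie fell by 2.18, the cytochrome P450 genes Cyp6a9 and Cyp6a23 by 1.69 and 1.36, the glutamate-gated chloride channel gene GluClalpha by 1.38, brk, a repressor in Dpp signalling, by 1.38, SmydA-3 by 1.22 and tnc by 1.10 on the log2 scale. Cyp6a17 and Cyp6a23 are neighbouring copies that could share reads. Of 10044 genes, 87 were higher and 155 lower, and 427 did not overlap between the groups (4.25%, chance gives 0.794%). Without single libraries these counts became 50 and 96 (attp2 1-week library 2), 47 and 56 (3), 49 and 58 (4) and 56 and 82 (5). Among libraries labelled LamC RNAi they became 148 and 247 without library 4 and 49 and 59 without library 5. The lower count became 98 without library 1 and 89 without library 3. Without the 4 libraries with gut transcripts they were 38 and 37, and Cyp6a17, brk, SmydA-3 and tnc lost their calls (adjusted p = 0.0515, 0.0594, 0.155 and 0.139), with log2 fold changes of 0.91, −1.33, −1.19 and −1.03 that had stayed near those of all libraries. In the fit of only the 2 groups sosie lost its call (adjusted p = 0.0621), and without a filter on low counts Cyp6a23 did (0.0534). The cut of called genes at a log2 fold change of at least 1 in size, which is not a test, left out Sr-CI, jtb and Cyp6a17, whose changes are smaller. With single libraries left out, sosie lost its call without attp2 1-week library 3 or 4 or LamC RNAi library 5 (adjusted p 0.0512 to 0.0613). The genes brk and SmydA-3 lost theirs without attp2 1-week library 2, 3, 4 or 5 or LamC RNAi library 1, 3 or 5 (0.0535 to 0.0754 and 0.0664 to 0.0819). Cyp6a23 lost its call without any of these 7, LamC RNAi library 2 or attp2 5-week library 1, 2 or 4 (0.0511 to 0.114), and tnc lost its call without those 7, attp2 1-week library 1, LamC RNAi library 4 or attp2 5-week library 1 (0.0518 to 0.102).

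Mitochondrial genes shifted down in the libraries labelled LamC RNAi. Of 57 oxidative phosphorylation genes 22 were lower and 0 higher (46 when adjusted over the list alone, median −0.24, camera adjusted p = 1.6e-32, adjusted p = 0.152 with an estimated correlation). Without the 4 libraries with gut transcripts 2 of 57 were lower past the threshold, with a median of −0.21. Their sum was 14115 ± 431 against 16362 ± 522 CPM (SD, n = 5 each). The succinate dehydrogenase genes SdhA and SdhD fell by 0.43 ± 0.06 and 0.40 ± 0.06, and UQCR-C1 and UQCR-C2 by 0.37 and 0.35 on the log2 scale. The TCA cycle had 2 lower of 10, muc and Acon (4 when adjusted over the list alone, camera adjusted p = 1.9e-05, adjusted p = 0.171 with an estimated correlation). Glycolysis had 0 of 19 past edgeR's threshold, also when adjusted over the list alone, with 5 at an unadjusted p under 0.05, 1 with DESeq2 and a median of −0.19. Lipid metabolism had wal, scu and CG7834 lower, which serve fatty acid oxidation, and the sterol carrier gene Npc2a higher of 32 (4 and 1 when adjusted over the list alone). Both had a camera adjusted p = 4.5e-04, and an adjusted p = 0.455 with an estimated correlation. Of 31 proteasome genes 0 passed edgeR's threshold over all genes, 29 had an unadjusted p under 0.05 and 2 passed DESeq2. When adjusted over the list alone, 29 were lower (median −0.37, camera adjusted p = 5.1e-13, adjusted p = 0.455 with an estimated correlation). Rpn8 was at −0.41 and Prosbeta6 at −0.45. The antioxidant list had 1 lower of 38, Sod2 (−0.30), and 1 when adjusted over the list alone (median −0.20, camera adjusted p = 0.0481, adjusted p = 0.455 with an estimated correlation). The other 10 biology lists did not pass camera. Cardiac transcription factors had tin (−0.70) and bap (−0.65) lower of 19, which sit side by side on chromosome 3R (3 when adjusted over the list alone, camera adjusted p = 0.692 downward, with a median of 0.11). The sarcomere had TpnC47D higher (0.85) of 27, also when adjusted over the list alone (median 0.07, camera adjusted p = 0.164). The matrix list had wb and the laminin gene LanB2 (0.51) higher of 27 (8 higher and 2 lower when adjusted over the list alone, camera adjusted p = 0.0954). Ion channels had Shab (0.49) higher of 31 (3 higher and 4 lower when adjusted over the list alone, camera adjusted p = 0.460). No member passed edgeR's test, over all genes or adjusted over the list alone, in the lamina (24 genes, camera adjusted p = 0.0657), immune (41, 0.483) and chaperone lists (22, 0.114). The same holds for the ribosomal (80, 0.788, median −0.01, mean 0.05), autophagy (23, 0.322) and clock lists (8, 0.124). In this order 8, 5, 2, 3, 4 and 1 members had an unadjusted p under 0.05, and 0, 3, 1, 1, 0 and 0 passed DESeq2. The stress peptide gene TotC was at 19.5 and 177 CPM (adjusted p = 0.105). Haemocyte markers moved the other way from age. NimC1 and Sr-CI were higher of 15 (4 when adjusted over the list alone, median 0.31, camera adjusted p = 3.5e-04, adjusted p = 0.0727 with an estimated correlation). The sum of the list was 5321 ± 908 against 3936 ± 374 CPM. NimC1 and Sr-CI both lie on chromosome 2L, which had the largest share of called genes of the 5 main arms (3.85%). A background linked to that arm cannot be told apart for these 2 genes. Of the other marker lists 1 gene passed, tnc of the 6 genes tested on the body wall muscle list (camera adjusted p = 0.687, median 0.06, mean −0.14). Nephrocyte (9 genes, 0.687), fat body (18, 0.687), neuron (9, 0.273), ovary (14, 0.687, downward with a median of 0.61), gut (20, 0.273, median −3.77) and Malpighian lists (5, 0.889) had 0 past edgeR's threshold. In this order 2, 4, 2, 0, 0 and 0 members had an unadjusted p under 0.05, and 1, 1, 1, 0, 0 and 0 passed DESeq2.

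**Figure D5:**
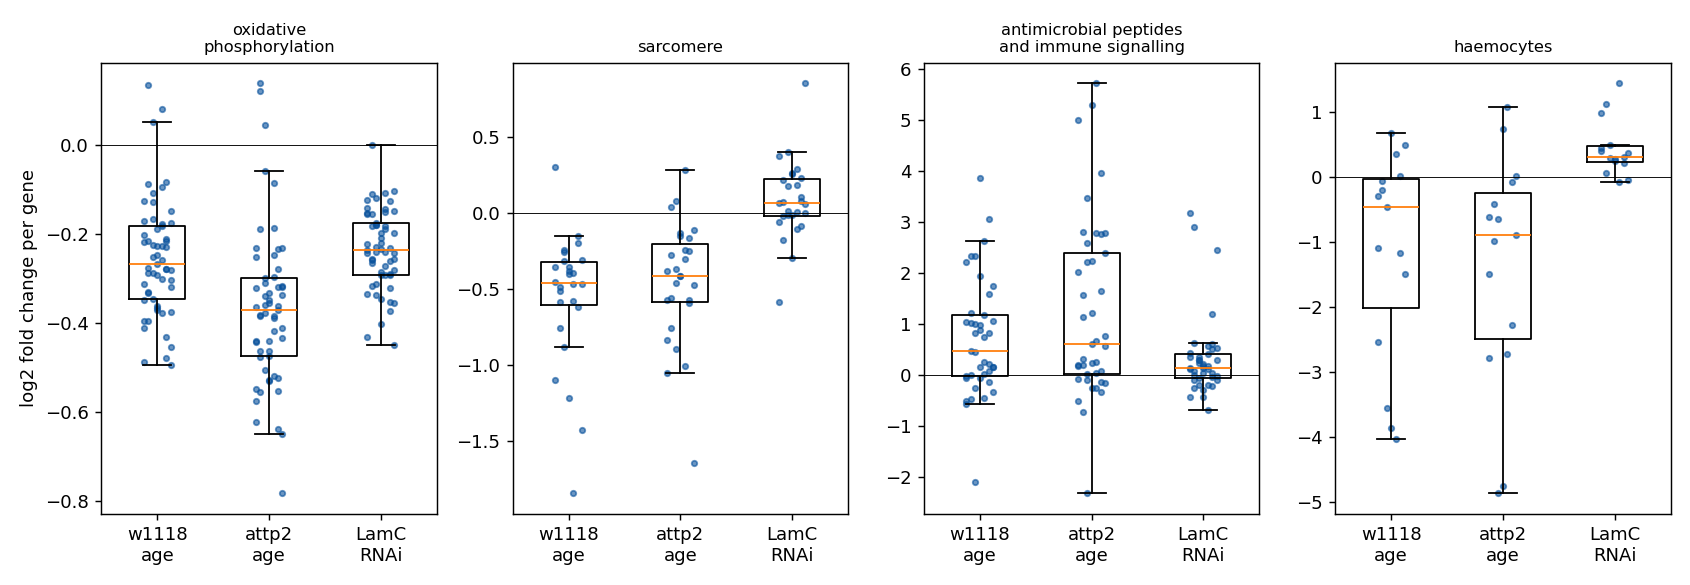
Log2 fold change of each tested member (points) of the oxidative phosphorylation, sarcomere, immune and haemocyte lists in 3 comparisons, with boxes at the quartiles, a line at the median and whiskers to the last member within 1.5 box lengths. Oxidative phosphorylation medians lie at −0.27, −0.37 and −0.24 with age in w1118, age in attp2 and LamC RNAi, while the sarcomere medians are −0.46, −0.41 and 0.07.

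The last purpose named was to find genes that age in attp2 and LamC RNAi change together. Of 10044 genes 31 were higher in both and 84 lower in both, where independent lists give 8.35 and 16.3 (exact hypergeometric p = 3.3e-11 and 3.4e-42), and 20 went opposite ways. By the size of the smaller change, the genes lower in both were led by ninaD (−2.66 with age, −2.62 with LamC RNAi), brk (−1.62, −1.38) and SmydA-3 (−1.75, −1.22). They were followed by Slob, a regulator of the slo channel (−0.85, −1.03), the arginine kinase gene Argk (−0.83, −0.76) and bap (−0.77, −0.65). The genes higher in both were led by MME1, a mitochondrial carrier gene (0.67, 0.53), CHKov1 (0.52, 0.65) and Psa (0.49, 1.29). Next came Rpb12, an RNA polymerase subunit gene (0.72, 0.45), Alg-2 (0.40, 0.48) and Zyx, the fly zyxin gene (0.41, 0.38). The hypergeometric p takes the 2 comparisons as unrelated. Both comparisons use the same 5 attp2 libraries at 1 week. In 40 simulations of unchanged groups against them, 0 genes were higher or lower in both, r across genes averaged 0.496 (0.447 to 0.574) and the covariance 0.130. The observed r was 0.118 (rho 0.232) and the covariance 0.0668, so that the covariance minus the simulated one was −0.0633. Across all genes the 2 comparisons thus showed no covariance beyond that of unchanged groups (0.104 to 0.156). With the controls split between the comparisons in 20 ways, 2.10 genes were higher in both on average (0 to 10, independent lists give 1.02). On average 15.8 were lower in both (4 to 53, independent lists give 2.72). In these splits r averaged −0.132 (−0.472 to 0.222) and the covariance −0.217. Genes lower in both thus stood above independent lists on average also when no control was shared. The simulated count of 0 says little, since few genes can be called in unchanged groups. Part of either excess may still come from the shared controls, which these values do not decide. Age in w1118 shares no library with LamC RNAi, and there 6 of 9444 genes were higher in both (4.21 for independent lists, exact hypergeometric p = 0.244) and 24 lower in both (5.59, p = 1.2e-09). The counts of 31 and 84 moved by over 1.5 times without single libraries. They became 12 and 50 (attp2 1-week library 2), 15 and 28 (3), 17 and 31 (4) and 17 and 40 (5). They became 17 and 44 (LamC RNAi library 1), 48 and 127 (4) and 14 and 36 (5). The higher count alone became 15 without attp2 5-week library 1 and 19 without library 5, and the lower count 49 without LamC RNAi library 3. They were 7 and 16 without the 4 libraries with gut transcripts.

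Compared directly with attp2 at 5 weeks, the libraries labelled LamC RNAi differed in 1930 genes, 1011 higher and 919 lower, and 1127 of 10044 genes did not overlap (11.2%, chance gives 0.794%). The 2 groups differ in age, 1 week against 5 weeks, as well as in label. No difference in this comparison can be credited to either alone. Of 16 biology lists 13 passed camera, and 0 with an estimated correlation. The sarcomere had 18 higher of 27 (20 when adjusted over the list alone, camera adjusted p = 9.8e-12, adjusted p = 0.283 with an estimated correlation). Oxidative phosphorylation had 26 higher and 1 lower of 57 (28 and 1 when adjusted over the list alone, median 0.16, camera adjusted p = 1.0e-06, adjusted p = 0.375 with an estimated correlation). Immune genes had 16 lower and 3 higher of 41 (17 and 4 when adjusted over the list alone, camera adjusted p = 6.3e-04, adjusted p = 0.388 with an estimated correlation). The proteasome had 18 lower of 31 (30 when adjusted over the list alone, camera adjusted p = 3.5e-10, adjusted p = 0.375 with an estimated correlation). Ribosomal protein genes had 18 higher of 80 (camera adjusted p = 3.2e-10), glycolysis 6 of 19 (2.2e-05), the matrix list 12 higher and 1 lower of 27 (3.3e-05), lipid metabolism 8 higher and 1 lower of 32 (0.00273) and the TCA cycle 4 higher of 10 (0.00989). Antioxidant genes had 9 lower of 38 (0.00346), cardiac transcription factors 2 higher of 19 (0.0131), ion channels 10 higher and 1 lower of 31 (0.0337) and the lamina list 5 higher and 1 lower of 24 (0.0378). With an estimated correlation the adjusted p of these 9 lists were 0.283 for the matrix, 0.380 for ribosomal proteins and lipids and 0.375 for the others. Markers of other cells moved beside these lists. Haemocyte genes had 11 higher and 1 lower of 15 (12 and 2 when adjusted over the list alone, median 1.60, camera adjusted p = 1.4e-09), and theirs was the only list here that also passed with an estimated correlation (adjusted p = 0.00315). Fat body and oenocyte genes had 5 higher of 18 (6 when adjusted over the list alone, median 0.71, camera adjusted p = 0.00861, adjusted p = 0.535 with an estimated correlation).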

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

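The tests of sarcomere genes, of blood cell classes and other tissues, of LamC RNA from other cells, and of neighbouring genes and chromosome arms were chosen only after the result was seen.

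Oxidative phosphorylation genes had a median log2 fold change of −0.24 in the libraries labelled LamC RNAi and of −0.37 at 5 weeks in attp2. The tables argue against gut RNA in 4 libraries as the source: without these the medians were −0.21 (57 of 57 members below 0, exact permutation p of the list mean 0.0286) and −0.40 (55 of 57, exact permutation p = 0.0286), with 2 and 47 members past the threshold among fewer libraries. For LamC RNAi they also argue against a smaller share of muscle cells, since the sarcomere median was 0.0656 and the sarcomere mean lay above the oxidative phosphorylation mean by 0.31 on the log2 scale (exact permutation p = 0.0238). For age, a smaller share of muscle cells stays open, since the sarcomere median was −0.41 and the difference of means −0.11 (exact permutation p = 0.262). A fall of these transcripts within heart cells, with age or through Lamin C RNAi, also stays open and could not be tested here. Shares of other tissues, such as oenocytes and fat body, were not tested as a source.

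Haemocyte genes were lower at 5 weeks in both strains, with medians of −0.89 in attp2 and −0.46 in w1118. A smaller amount of all tissue around the heart alike is argued against by the neuron list, whose medians of 0.05 in attp2 and 0.31 in w1118 lay above the haemocyte medians by more than the SD over its members (0.358 and 0.348, exact permutation p of the difference of list means 0.00794 and 0.0286). That difference also holds the fall of PPO1 and PPO2, which pull the haemocyte mean down. Neuron genes stood at a low level, with a sum that went from 69.8 to 55.2 CPM in attp2 and from 68.9 to 66.0 CPM in w1118. Their mean log2 fold change in attp2 was −0.11, so a smaller loss of neuron RNA stays open there. Of the neuron, nephrocyte (−0.10) and fat body (−0.46) medians in attp2, 2 of 3 lay nearer to 0 than to the haemocyte median, so less fat body stays open there. A loss of all haemocytes alike cannot be told apart from a loss that was greater in crystal cells. PPO1 and PPO2 changed by −4.63 on the log2 scale relative to 5 plasmatocyte genes in attp2 (exact permutation p = 0.00794). In w1118 that change was −3.46 (exact permutation p = 0.0286). These 2 genes are among those that fell furthest and so decide nothing. The plasmatocyte genes themselves changed by a mean of −0.93 in attp2 (exact permutation p = 0.00794) and −0.71 in w1118 (exact permutation p = 0.0286). Their fall argues against a loss of crystal cells alone. Fewer haemocytes with age and a change of expression within these cells both stay open, the latter untested.

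LamC was not measurably lower in the libraries labelled LamC RNAi (adjusted p = 0.628), although 242 other genes differed from attp2 at 1 week. A swap of single libraries between the groups is argued against, since 10 of 10 libraries lay nearer to their own group over 100 genes chosen without them, while an exchange of all 5 would give the same and stays open. LamC RNA of cells that do not express the RNAi cannot be told apart from a weak knockdown (adjusted p = 0.628, 95% bounds −0.64 and 0.24), and reads of the hairpin counted as LamC were not tested. With LamC RNAi the share of called genes ran from 3.85% on 2L to 1.42% on 3R over the 5 main arms (permutation p = 1e-04, the smallest that 10000 draws can give, against 0.787 and 0.673 for age in w1118 and attp2). This is what a genetic background that differs on some chromosome arms predicts. It still cannot be told apart from an effect of the RNAi, since arms can be unequal within 1 background. With chromosome 4 (9.41% with LamC RNAi) included, age in attp2 was unequal too (41.2% on chromosome 4, permutation p = 1e-04). Background on shorter stretches cannot be told apart, since neighbouring pairs of called genes exceeded chance in all 3 comparisons. With LamC RNAi there were 14 (5.70 by chance, permutation p = 0.0012) and with age in attp2 480 (401 by chance, permutation p = 1e-04, again the smallest). Age in w1118 gave 90 (75.9 by chance, permutation p = 0.0453). Relative to chance the excess was largest with LamC RNAi, and an effect of Lamin C RNAi itself stays open.

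Whether chance can be excluded was read from other splits of the same libraries. It can for w1118 age (502 higher and 356 lower, 1 of 35 splits as large, highest other 0), attp2 age (964 and 1054, 1 of 100, highest other 24), and LamC RNAi against attp2 at 5 weeks (1930 genes, 1 of 100, highest other 67). The splits do not test the genes shared by the strains (213 and 189, highest other 0) or by attp2 age and LamC RNAi (31 and 84, highest other 0), since most other splits call 0 genes in each comparison and so can share none. For LamC RNAi (87 and 155) 2 of 100 splits were as large, the highest other with 233 genes in its larger direction, a split that exchanged attp2 1-week library 1 for LamC RNAi library 4. For the strain difference (79 genes) 2 of 100 were as large, the highest other with 132 genes. By its share of 2 of 100 the real split of LamC RNAi is rare, but another split called more genes than the real one. The splits alone therefore do not exclude chance for LamC RNAi, and why that split called more was not tested. The splits for the strain difference exchanged ages within each strain, which also takes away the age effect that the strains share. They therefore do not test the difference alone, and chance is not excluded for it. For the number of biology lists past camera chance cannot be excluded: 5 of 35 splits gave as many as the 10 in w1118, 15 of 100 as many as the 10 in attp2 and 62 of 100 as many as the 6 with LamC RNAi, with a highest other of 12 in each. The median over the other splits was 5.5, 6 and 6 lists, so camera with the preset correlation passes lists also where the groups are mixed.

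The age effect differed between the strains for 79 genes by the interaction test. The differences on the log2 scale, attp2 minus w1118, were 3.31 for DNApol-delta, 0.92 for bor, 0.82 for ValRS, 0.96 for Keap1, −1.70 for Kaz1-ORFB, −1.31 for Men, −0.87 for Drak and −0.64 for uzip. By camera, 5 biology lists differed, with adjusted p = 0.00283 for oxidative phosphorylation (median −0.12) and for the TCA cycle (−0.21), 1.8e-06 for glycolysis (−0.35), 1.9e-09 for lipid metabolism (−0.36) and 0.00750 for the proteasome (0.18), all with an adjusted p = 0.772 with an estimated correlation. Marker lists differed for fat body and oenocytes (median −0.87, adjusted p = 1.5e-05, and 0.305 with an estimated correlation) and for ovary and eggs (median −2.66, adjusted p = 0.00658, and 0.450 with an estimated correlation). Strain and table cannot be told apart.

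Single libraries stood far from the others of their group in 29 of 247 values looked at (11.7%) by Dixon's test, which picks about 1 in 20 groups by chance. Library 1 of w1118 at 5 weeks had 21.8 M counts. In attp2 1-week library 3, summed CPM were 13623 for gut, 197 for ovary, 57.8 for Malpighian tubule and 0.151 for histones. In LamC RNAi library 3 they were 689 for ovary, 42.0 for Malpighian tubule and 0.0957 for histones. Gut genes summed to 19021 CPM in attp2 5-week library 3 and ovary genes to 282 CPM in library 4. Histones summed to 0.0757 CPM in w1118 1-week library 3 and to 0.122 CPM in 5-week library 3. Sarcomere genes summed to 18266 CPM in attp2 1-week library 5, which had 72.8 CPM of tnc. Autophagy genes summed to 4161 CPM in attp2 1-week library 1, which had 152 CPM of Drs. In attp2 1-week library 4, male tract genes summed to 5.73 CPM, with 139.5 CPM of DptA, 7.95 of SPH93 and 0.862 of phr. In attp2 5-week library 2, PPO2 was at 72.5, PPO1 at 76.8 and Cpr49Ae at 4.27 CPM. Cyp6a9 was at 29.5 CPM in LamC RNAi library 5. In w1118, PGRP-SC1b was at 2.27 CPM in 1-week library 3, RpS5b at 1.41 and GstD5 at 16.8 CPM in 1-week library 4, RpS5b at 33.8 CPM in 5-week library 2 and Obp56d at 35.1 CPM in 5-week library 3.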

How the results depend on the processing

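The removal of the libraries with gut transcripts and the gut and heat shock covariates were tests chosen only after the results were seen. No value past the threshold turned direction, and 1085 of 1149 values of single genes kept their side of the threshold, 61 lost it and 3 gained it, all 3 for LamC in w1118. These genes were LamC, Lam and those named for the largest fold changes, which were chosen past the threshold and without overlap. Such a choice favours stability, and many counts over all genes moved by over 1.5 times under other settings, as given below. With DESeq2 size factors and the gut covariate no count moved by over 1.5 times. Small changes were mostly missed at these numbers of libraries and this spread between them: in simulated data 16%, 14% and 22% of 1.5-fold changes were found for w1118 age, attp2 age and LamC RNAi. Depth was not varied.

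In the values below the cause was not tested, except that a size limit leaves fewer genes by construction. DESeq2 gave 845 higher and 732 lower for w1118, 293 and 399 for LamC RNAi, 345 and 387 for both strains, 96 and 184 for age with LamC RNAi and 435 for the strain difference. With a log2 fold change of at least 1 in size there were 253 and 118 for w1118, 266 and 215 for attp2, 28 and 34 for LamC RNAi, 91 and 48 for both strains, 9 and 7 for age with LamC RNAi, 50 for the strain difference and 552 for LamC RNAi against 5 weeks. Without a filter 17 genes were higher with age and LamC RNAi, and the 5 CPM filter gave 133 for the strain difference. Fits of only 2 groups gave 72 lower for LamC RNAi and 12 and 41 for age with LamC RNAi. Without the 4 libraries with gut transcripts there were 38 and 37 for LamC RNAi and 7 and 16 for age with LamC RNAi, and the heat shock covariate gave 138 for the strain difference. Of the biology lists, 0, 0 and 0 passed with an estimated correlation in w1118, attp2 and LamC RNAi, while 1 passed fry in w1118 (autophagy, which had not passed camera) and 2 in LamC RNAi.

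With the replicate number as a block, 176 genes differed between the strains and 10 biology lists passed for LamC RNAi; no other count moved by over 1.5 times. LamC with age in attp2 had an adjusted p = 0.0872 with the block (0.362 without). Same-numbered libraries deviated together only in part, 4, 3 and 4 of 5 pairs over 0.1 in the attp2 table and 1 of 4 in w1118, so the numbers were not taken to pair them: correlations ran from −0.14 to 0.85 between the attp2 ages, 0.07 to 0.60 between attp2 at 1 week and LamC RNAi, −0.10 to 0.57 between attp2 at 5 weeks and LamC RNAi and −0.01 to 0.15 in w1118, and in no pair of groups did each library match its own number best.

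With each library left out in turn, ranges were 174 to 578 higher and 124 to 512 lower in w1118, 690 to 1105 and 788 to 1158 in attp2, 47 to 148 and 56 to 247 for LamC RNAi, 88 to 235 and 76 to 199 for both strains, 12 to 48 and 28 to 127 for age with LamC RNAi, 11 to 271 for the strain difference, 1457 to 2133 for LamC RNAi against 5 weeks, and 5 to 11, 10 to 11 and 5 to 8 biology lists in w1118, attp2 and LamC RNAi.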

Other observations

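All tests in this part were chosen only after the result was seen, and none offers an explanation.

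On the small chromosome 4, 35 of 85 tested genes passed the threshold with age in attp2 (41.2%) and 8 of 85 with LamC RNAi (9.41%), against 8 of 86 with age in w1118 (9.30%). On the other arms the shares with age in attp2 ran from 19.0% on 3R to 20.5% on 2L. Within 1 Mb of LamC, 8 of 183 tested genes passed with LamC RNAi, among them the cytochrome P450 genes Cyp6a17 (2R from 14873953 to 14875739), Cyp6a23 and Cyp6a9, and Rpb12. The 1 Mb window with most called genes lay on 2L from 1872455 to 2872455, with 12 of 93.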
